A study of Homo sapiens with 6 samples.

How the data were processed

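Transcript abundance was measured by RNA sequencing in 6 samples of the human esophageal squamous carcinoma line KYSE450, 3 with a control vector (shVec) and 3 with a short hairpin RNA against SOX2 (shSOX2). Per the labels' protocols, hairpins were carried by pLKO lentiviral plasmids, stable lines were selected with puromycin for 1 week, RNA came from equal numbers of cells, yeast RNA (10%) was added to each RNA sample, libraries were made with a stranded mRNA kit, and sequencing was on an Illumina NovaSeq instrument. The labels do not say whether the replicates of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical. The labels name no hairpin sequence and 1 shSOX2 line, so a hairpin effect cannot be separated from an effect of SOX2 by a comparison of hairpins.

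The authors deposited 1 table of raw counts per gene for the 6 samples, with the summed exon length of each gene in bases, the other measure, per the file headers. Per the submitters' processing notes, FastQC, STAR 2.6.0c, featureCounts 2.0.3 and DESeq2 were used, with the builds hg19 and sacCer3. The deposited counts are whole numbers with no normalization, and gene coordinates are on hg19. The strand and multi-mapping settings of the counting are not given in the sources used here, so reads of a gene and an overlapping antisense gene may not be separable, and genes with near-identical copies are uncertain. All 57905 rows carried human gene identifiers. The planned scaling by yeast reads and the planned comparison of yeast read shares were not run, and yeast counts were not analysed here. Absolute RNA amounts per cell were therefore not estimated, and every fold change is relative to the other human genes. Gene symbols and types were taken from GENCODE release 29 by identifier, which gave a symbol to 52338 of the 57905 identifiers. Its GRCh38 coordinates were not used. Identifiers without a symbol held 0.61% to 0.64% of the counts of a library. 6 list symbols matched no row by this lookup and were not used here, among them ACACA, TADA2A, UHRF1, CCL5 and PECAM1. Their genes may stand among the identifiers without a symbol.

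Total counts ranged from 34206804 to 40999092 per library, and 3 counts, the upper limit that a count of 0 allows, correspond to 0.0732 to 0.0877 CPM. Intervals and floors cover counting error only. Between 21765 and 24030 genes had a count. Libraries of a group were compared before averaging: their log2 CPM correlated at r = 0.979 to 0.997 across genes, against 0.89 to 0.95 between groups, and a chi-square test over genes with at least 20 counts gave at least 5.40 per gene for every pair within a group, so no pair agreed within sampling noise and all 6 were kept as separate samples.

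The main test was the edgeR (4.0.16) quasi-likelihood F test with robust dispersion, TMM scaling factors and the filterByExpr filter, without covariates, and Benjamini-Hochberg adjustment over the 17012 genes kept. A gene was called at an adjusted p under 0.05, and changes of at least 2-fold were counted with an absolute log2 fold change of at least 1. Biological coefficient of variation was 13.3%. Standard errors are the absolute log2 fold change divided by the square root of F. CPM values are counts relative to the TMM-scaled library total, with SDs over the 3 libraries of a group. The smallest p that an exact permutation test of 3 against 3 libraries can give is 0.1, so adjusted p-values from edgeR rest on its model of the spread across genes. Gene lists were tested with camera (limma 3.58.1) with a preset correlation between genes of 0.01 and, as alternatives, with an estimated correlation and with fry, Benjamini-Hochberg adjusted over 32 lists. For DESeq2 and for the length and GC offsets, camera was run in its preranked form, on signed test statistics rather than counts. List p-values from those settings therefore differ from the main ones in the form of the test as well. All adjusted p-values in the text are Benjamini-Hochberg adjusted, over genes for edgeR and over lists for camera.

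The code was tested on 10 simulated data sets for the comparison of shSOX2 with shVec, drawn from the real means and library sizes with 200 changed genes each, on 16601 to 16654 genes. It called 96.75% of genes simulated at a log2 fold change of -2, 81.0% at -1, 33.25% at -0.5, 19.75% at 0.4 and 91.25% at 1. Of 1379 calls, 6.60% were false. Camera called the lowered set in 10 of 10 draws and had p under 0.05 for 3 of 500 random sets. Genes were drawn independently of each other, so these draws do not measure camera's error on lists of correlated genes. In the real data the estimated correlation reached 0.67, in the oxidative phosphorylation list.

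The genes named in the text follow a rule fixed in advance: SOX2 first; the 10 largest rises and 10 largest falls among called genes with a symbol, a mean of at least 5 CPM and groups that do not overlap; TP63, KLF5, ACSL5, ACLY, ACSS2, FASN, SCD, CPT1A, EP300, KAT2A and HDAC1; up to 3 members with the lowest adjusted p of each passing list and of the lipid, acetyl-CoA and acetylation lists; and up to 2 called members of the other lists. Genes named outside it are said to have been chosen after their values were seen. Some genes that the rule takes are not reported here. The lists were fixed from textbook knowledge and the series title. They covered fatty acid synthesis, activation and oxidation, cholesterol, triglyceride, phospholipid and sphingolipid genes, acetyl-CoA supply, histone acetyltransferases, deacetylases and acetyl-histone readers, epithelial, mesenchymal and stem cell identities, cell cycle, ribosome biogenesis, glycolysis, oxidative phosphorylation, stress responses, signalling, and markers of leukocytes, fibroblasts and endothelium.

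Alternatives planned in advance were DESeq2 size factors in edgeR, upper-quartile factors, the DESeq2 (1.42.0) Wald test, limma-voom, no low-count filter, a filter at 1 CPM in 3 libraries, the replicate number as a block, and leaving out each library. Alternatives added after seeing the data were total counts without scaling factors, smooth per-library offsets (mgcv 1.9.3) for gene length, for GC content of the longest transcript and for both, and leaving out shVec replicate 3 and shSOX2 replicate 3 together, the libraries farthest out on the length trend. GC content was known for 97.1% of tested genes. Python 3.11.15 with scipy 1.17.1 was used for exact tests and matplotlib 3.10.9 for plots, and R 4.3.3 for model fits.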

Results

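RNA sequencing was used to compare KYSE450 cells, an established line of human esophageal squamous cell carcinoma, carrying either a short hairpin RNA against the transcription factor SOX2 (shSOX2) or a control vector (shVec). Lentivirus delivered the constructs, and stable lines were obtained by 1 week of puromycin selection. Each group had 3 libraries, so n = 3 for every group mean below. The total count per library was 36311742, 35858898 and 40999092 for shVec replicates 1, 2 and 3, and 38427332, 40362749 and 34206804 for shSOX2 replicates 1, 2 and 3. Mitochondrially encoded genes took 6.67% ± 0.37 (SD) of the counts in shVec and 8.29% ± 0.35 in shSOX2, with every shSOX2 library above every shVec library (two-sided exact permutation test, p = 0.1, the smallest value that 3 against 3 libraries allow). The series title ties SOX2 to lipid metabolism and histone acetylation, and the comparison asks which transcripts differ when SOX2 is targeted.

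SOX2 was measured first as a check on the labels. Its transcript (ENSG00000181449, hg19 chromosome 3, 181429714 to 181432221, plus strand, 2508 exonic bases) had 5710, 5698 and 7056 counts in the shVec libraries and 5156, 5844 and 4190 counts in the shSOX2 libraries. After scaling, SOX2 was at 170.2 ± 5.57 CPM (library-scaled counts, SD) in shVec and 128.0 ± 7.99 CPM in shSOX2, a fall that all 3 shSOX2 libraries shared. The log2 fold change was -0.41 ± 0.08 (SE; edgeR adjusted p = 0.00166), or 24.8% lower with a 95% confidence interval of 16.4% to 32.3%. The interval is a normal approximation with the main scaling. It may therefore be too narrow for 3 libraries a group, and it leaves out the choice of scaling. The direction fitted the labels, but the size was modest beside other genes: 3090 of the 4003 genes called lower fell by more on the log2 scale. The SOX2 log2 fold change was -0.25 with upper-quartile scaling and -0.68 with an offset for gene length, both outside the interval above.

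Of 17012 genes tested, 7974 (46.9%) passed an adjusted p of 0.05, 3971 higher and 4003 lower in shSOX2. At a fold change of at least 2, the split was uneven, with 1827 genes higher and 738 lower. The lower count was 488 with upper-quartile scaling and 554 to 1008 with a library left out, and the higher count ranged from 1328 to 2306 over all alternatives. The 2 groups did not overlap in 56.3% of tested genes, against the 10% that chance gives for 3 against 3 libraries. Higher genes made up 49.8% of the calls with the main scaling, 66.8% with upper-quartile scaling and 65.0% with total counts alone, where the median of all genes moved by 0.16 and 0.13 on the log2 scale. They made up 37.6%, 36.4% and 37.8% of the calls with offsets for gene length, GC content and both, which moved that median by -0.13, -0.10 and -0.11. The balance of higher against lower genes therefore rested on the scaling, and the directions below are relative to the main one.

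Gene lists were fixed before the data were examined, and 15 of 32 passed the set test, 8 higher and 7 lower. With an estimated correlation between genes, 3 passed: basal squamous identity, ribosome biogenesis and cholesterol synthesis. A pass lost in that setting need not come from correlation between genes. The columnar (-0.04), mesenchymal (-0.02), p53 (-0.02) and G1/S (0.0088) lists had estimates under the preset 0.01 and lost their pass as well. In the other lists that lost it, the estimate was above 0.01. Member counts below are with the main scaling and over all genes tested. Whether more members were higher or lower turned with upper-quartile scaling in fatty acid synthesis, glycolysis and p53 targets, and with both offsets in the peroxisomal, triglyceride, oxidative phosphorylation, NF-kB and growth factor lists. Adjusted over the list alone, 21 lists gave equal counts. Of the other 11, the members called lower were 16 in cholesterol synthesis, 14 in squamous terminal differentiation, 27 in G1/S and DNA replication, 17 in G2/M and mitosis, 26 in ribosome biogenesis and 12 in sphingolipid metabolism. The members called higher were 7 in fatty acid synthesis, 13 in mitochondrial fatty acid oxidation, 12 in hypoxia response, 2 in oxidative phosphorylation and 1 among leukocyte markers.

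Genes of squamous epithelial identity fell together. Of 33 tested genes of the basal squamous list, 29 fell and 1 rose (camera adjusted p = 3.17e-43, and adjusted p = 0.0030 with an estimated correlation). TP63, the master regulator of the squamous lineage (chromosome 3, 189349205 to 189615068), went from 401.7 ± 69.5 to 205.9 ± 28.6 CPM, a log2 fold change of -0.96 ± 0.14 (edgeR adjusted p = 0.000294). KLF5, a transcription factor of proliferating epithelium, fell from 94.3 ± 10.0 to 42.6 ± 5.03 CPM (log2 fold change -1.14 ± 0.11). Keratins of the basal and hyperproliferative layers fell as well. KRT6A, the most abundant of them among the named genes, went from 7999 ± 453 to 562 ± 18.4 CPM, and KRT14, a basal layer keratin, from 1816 ± 263 to 155.9 ± 18.4 CPM. KRT16 (log2 fold change -4.20), KRT6B (-4.30) and KRT6C (-3.41) also fell. KRT6A, KRT6B and KRT6C are near-identical paralogs, so how reads were divided among them is uncertain. The desmosome component PKP1 fell by 2.31 on the log2 scale. The receptor FGFR3 was the 1 member that rose (0.71), and GRHL2 (0.14), FGFR2 (-0.13) and TFAP2C (0.10) did not pass, all 4 being named after their values were seen.

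Terminal differentiation genes of squamous epithelium moved less uniformly. Among 24 tested, 13 fell and 4 rose (camera adjusted p = 7.12e-05, and adjusted p = 0.0622 with an estimated correlation). SPRR1B, a precursor of the cornified envelope, fell from 39.8 ± 6.34 to 1.36 ± 0.32 CPM, the largest fall among the named genes (log2 fold change -4.88). KRT13, a keratin of the suprabasal esophagus, went from 2190 ± 224 to 381.4 ± 27.3 CPM, and the membrane protein EMP1 fell by 3.15 on the log2 scale. The 4 members that rose, named after their values were seen, were CSTA (1.48), PPL (0.85), SCEL (0.91) and CNFN (1.02).

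**Figure D1:**
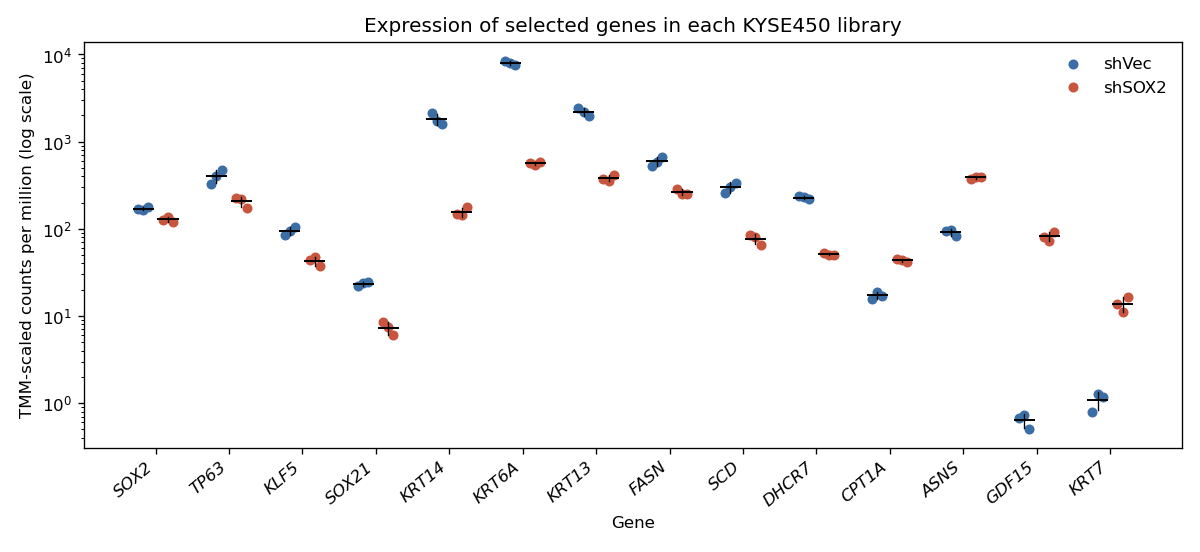
Scaled CPM (log axis) of 14 genes in each of the 6 KYSE450 libraries. Points are libraries, horizontal bars are group means and vertical bars are 1 SD; KRT6A libraries lie between 7525 and 8426 CPM in shVec and between 544 and 581 CPM in shSOX2, while SOX2 libraries lie between 165.2 and 176.2 CPM and between 120.7 and 136.5 CPM.

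The columnar and mesenchymal lists passed in the upward direction. Only 13 of 33 genes of columnar and glandular epithelium could be tested, of which 5 rose and 1 fell (camera adjusted p = 0.0325, and adjusted p = 0.182 with an estimated correlation). KRT7, a keratin of simple epithelium, rose from 1.08 ± 0.25 to 13.8 ± 2.78 CPM, the mucin MUC1 from 0.54 ± 0.04 to 2.54 ± 0.31 CPM and the secretory protein AGR2 from 28.7 ± 3.31 to 62.7 ± 4.42 CPM. MUC1's log2 fold change of 2.24 was 1.22 with an offset for GC content. KRT18 (0.52) and TFF3 (3.05) rose and HNF4G (-1.93) fell, named after their values were seen. The other 7 tested members did not pass. Among them was KRT8, at 2392 ± 263 CPM in shVec and 2651 ± 261 CPM in shSOX2 (0.15), also named after its values were seen. The call of this list ended with limma-voom (adjusted p = 0.114) and with the GC offset (0.0765; 0.0847 with both offsets). Of 21 tested mesenchymal genes, 11 rose and 4 fell (camera adjusted p = 0.00049, and adjusted p = 0.0622 with an estimated correlation). The receptor kinase AXL rose from 46.2 ± 2.79 to 152.7 ± 2.82 CPM, with MMP14, a membrane-bound matrix protease, and COL6A1, a collagen chain, rising by log2 fold changes of 1.93 and 1.91. The 4 that fell, named after their values were seen, were SNAI2 (-0.52), MMP2 (-0.72), CDH2 (-0.78) and TGFBI (-0.85). Among 23 tested stem cell and SOX family factors, 9 fell and 2 rose, SOX12 (0.80) and NES (1.85), named on sight of their values, and the list did not pass (camera adjusted p = 0.0927), though it did with DESeq2 (0.0156), no low-count filter (0.0273), the GC offset (0.0159) and both offsets (0.0174), and not with an estimated correlation (adjusted p = 0.245). With upper-quartile scaling 5 of these factors were higher and 6 lower, and with both offsets 2 and 13. Fry, which does not compare a list with other genes, passed the list (adjusted p = 0.000555). SOX21, a SOX family member, fell from 23.4 ± 1.11 to 7.34 ± 1.22 CPM, and the adhesion receptor CD44 from 844.6 ± 12.1 to 392.6 ± 2.48 CPM.

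Among the lipid lists, cholesterol synthesis showed the clearest fall. Of 26 tested members, 15 fell and 1 rose (camera adjusted p = 2.07e-06, and adjusted p = 0.0495 with an estimated correlation). DHCR7, which catalyzes the last step of cholesterol synthesis in the Kandutsch-Russell route, fell from 228.2 ± 9.22 to 51.0 ± 1.51 CPM, a log2 fold change of -2.16 ± 0.08. TM7SF2, a sterol reductase named after its values were seen, was the 1 member that rose (1.77).

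Fatty acid genes went in both directions. In the list of fatty acid synthesis and desaturation, 6 of 25 tested members rose and 8 fell (8 and 4 with upper-quartile scaling), and the list did not pass (camera adjusted p = 0.464). FASN, the fatty acid synthase, nonetheless fell from 593.4 ± 67.7 to 263.1 ± 20.8 CPM (log2 fold change -1.17 ± 0.10), and SCD, the stearoyl-CoA desaturase, from 299.9 ± 40.5 to 76.8 ± 10.4 CPM (-1.97 ± 0.13). FADS3, of the fatty acid desaturase family, rose by a log2 fold change of 0.94. FASN's log2 fold change was -1.83 with the GC offset. Of 27 tested genes of mitochondrial fatty acid oxidation, 12 rose and 1, ACADM (-0.37, named after its values were seen), fell (camera adjusted p = 0.0308, and adjusted p = 0.394 with an estimated correlation). CPT1A, the carnitine palmitoyltransferase that admits long-chain acyl groups to mitochondria, rose from 17.2 ± 1.75 to 43.6 ± 1.55 CPM (1.34 ± 0.11), the thiolase ACAA2 from 0.57 ± 0.18 to 5.89 ± 1.33 CPM, and ECI1 by a log2 fold change of 0.95, which was 0.48 with the GC offset. Without shVec replicate 3 the call of this list ended (camera adjusted p = 0.0590), as it did without replicate 3 of both groups (0.0581) and with the length offset (0.0509).

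The acyl-CoA synthetases moved apart. ACSL5 (chromosome 10, 114133776 to 114188138) was near the floor of detection, with 2, 0 and 3 counts in the shVec libraries and 28, 25 and 16 in the shSOX2 libraries, a ratio of 12.6 with a 95% counting interval of 5.16 to 40.2 (edgeR adjusted p = 0.00247). ACSL3 and ACSL4 were far more abundant and fell, from 137.8 ± 8.25 to 72.5 ± 4.56 CPM and from 44.8 ± 5.94 to 17.9 ± 3.98 CPM, while the lipoprotein receptor VLDLR rose from 16.1 ± 0.80 to 44.6 ± 3.51 CPM. Over the list of fatty acid activation and uptake, 9 of 22 tested members rose and 6 fell (camera adjusted p = 0.555).

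The other lipid lists did not pass. Peroxisomal fatty acid oxidation had 6 members higher and 4 lower of 23 tested (camera adjusted p = 0.856), with a median log2 fold change of -0.09 and a mean of 0.03. There, CRAT, the carnitine acetyltransferase, rose by a log2 fold change of 1.28 (0.77 with the GC offset) and CAT, catalase, by 0.52 (0.33 with the length offset), while the import receptor PEX5 fell by 0.66; the other 3 that fell, named after their values were seen, were ABCD3 (-0.55), EHHADH (-0.59) and HSD17B4 (-0.29). Triglyceride and lipid droplet genes were split 10 higher to 8 lower of 27 (camera adjusted p = 0.856), the sign of the list turning with the GC offset. GPAT3 fell by 1.46 and SOAT1, which esterifies cholesterol, by 1.34 on the log2 scale, whereas DGAT2 of triglyceride synthesis rose by 1.71. Phospholipid genes had 4 higher and 8 lower of 25 (camera adjusted p = 0.163; 0.0362 with the GC offset), among them falls of CEPT1 (-1.15), LPCAT2 (-1.36) and LPCAT3 (-0.81). The 4 that rose, named after their values were seen, were MBOAT7 (0.56), LPCAT1 (0.21), ETNK2 (0.64) and PCYT2 (0.26). Sphingolipid genes had 7 higher and 10 lower of 32 (camera adjusted p = 0.399), with the sphingomyelinases SMPD1 (1.92) and SMPD4 (-0.68, and -1.12 with the GC offset) on opposite sides and the ceramide synthase CERS4 at 1.35.

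Genes that supply acetyl-CoA went both ways as well, with 5 of 22 tested higher and 10 lower (camera adjusted p = 0.376). ACLY, which makes cytosolic acetyl-CoA from citrate, fell from 447.0 ± 41.7 to 300.6 ± 24.4 CPM (log2 fold change -0.57 ± 0.09), and ACSS2, which makes it from acetate, rose from 13.3 ± 1.01 to 17.9 ± 0.49 CPM (0.43 ± 0.11). The call of ACSS2 ended with the GC offset (log2 fold change 0.20, edgeR adjusted p = 0.121). DLAT, a subunit of pyruvate dehydrogenase, fell by 0.74 and PDK2, a kinase that inhibits that enzyme, rose by 1.45. CRAT rose as well, as did PDK3 (0.46), named after its values were seen.

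Histone acetyltransferases and their cofactors fell as a list. Of 22 tested, 12 fell and 1, TADA3 (0.33, named after its values were seen), rose (camera adjusted p = 0.0308, and adjusted p = 0.545 with an estimated correlation). EP300 fell from 80.1 ± 23.9 to 48.9 ± 9.23 CPM (log2 fold change -0.71 ± 0.20, edgeR adjusted p = 0.0147). Its value was -0.47 without shVec replicate 3 and -0.33 without replicate 3 of both groups, and its call ended with total counts alone (edgeR adjusted p = 0.0544) and with the replicate number as a block (0.0507). KAT14 (-0.93), BRPF3 (-0.61) and the scaffold TRRAP (-0.79) also fell, and KAT2A, at 191.1 ± 19.7 against 176.3 ± 14.7 CPM, did not pass (-0.12 ± 0.10, edgeR adjusted p = 0.343). KAT2A stood at 0.04 with upper-quartile scaling and at -0.54 with the GC offset, where it was called, as it was with the length offset (-0.28) and without replicate 3 of both groups (-0.25). These are long genes, with a median of 7620 exonic bases over the list, and the list's call ended with the length offset (camera adjusted p = 0.0627), without shVec replicate 3 (0.0546), without replicate 3 of both groups (0.0807) and with a filter at 1 CPM (0.0698). With offsets for length and GC together the list passed narrowly (camera adjusted p = 0.0411).

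Acetyl-histone readers, of a median 9616 exonic bases, had 10 members lower and 1, CECR2 (1.54, named after its values were seen), higher of 20 tested, and did not pass (camera adjusted p = 0.0616). With DESeq2 (0.0057), limma-voom (0.0150) and no low-count filter (0.0066) the list did pass, as it did without either of shVec replicates 1 (0.0116) and 2 (0.0454) or shSOX2 replicates 1 (0.0281) and 2 (0.0354). The list did not pass with an estimated correlation (camera adjusted p = 0.649) or with fry (adjusted p = 0.0922), which does not compare a list with other genes. With upper-quartile scaling 4 members were lower and 1 higher. With offsets for length and GC together 12 members were lower and 3 higher, and the list did not pass (camera adjusted p = 0.308). ATAD2 (-0.77), MLLT1 (-0.70) and TAF1 (-0.87) fell. MLLT1 stood at -1.24 with the GC offset. ATAD2, TRRAP and TAF1 stood at -0.50, -0.52 and -0.53 without replicate 3 of both groups. Histone deacetylases and sirtuins were mixed, with 6 higher and 4 lower of 18 (camera adjusted p = 0.555), and the list's sign turned with the GC offset. HDAC1 rose from 194.8 ± 3.70 to 239.5 ± 3.56 CPM (log2 fold change 0.30 ± 0.07), a call that ended with the length offset (edgeR adjusted p = 0.0812). HDAC5 (0.76) and HDAC11 (0.98) rose, at 0.30 and 0.52 with the GC offset, and HDAC9 fell by 1.62 on the log2 scale. The other members that fell, named after their values were seen, were HDAC4 (-0.61), SIRT1 (-0.70) and HDAC2 (-0.20).

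**Figure D2:**
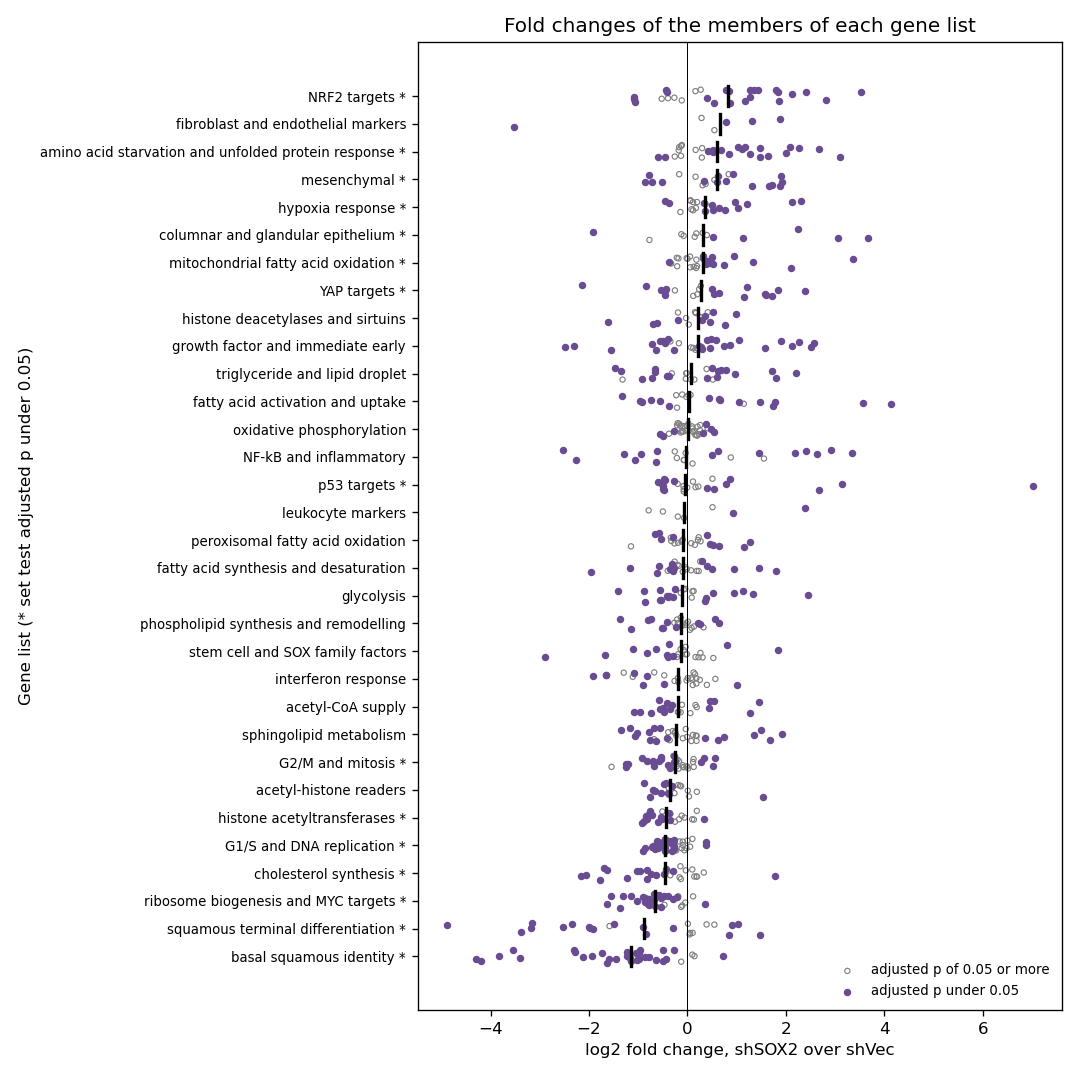
Log2 fold changes (shSOX2 over shVec, horizontal axis) of the tested members of 32 gene lists, ordered by median. Filled points have an edgeR adjusted p under 0.05, open points do not, black bars are list medians and asterisks mark lists that passed camera; the basal squamous list has the lowest median (-1.14) and the NRF2 list the highest (0.81).

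More ribosome biogenesis and cell cycle genes fell than rose. Of 32 ribosome biogenesis and MYC target genes, 25 fell and 1, NME1 (0.37, named after its values were seen), rose (camera adjusted p = 6.45e-13, and adjusted p = 0.0378 with an estimated correlation). The nucleolar proteins NCL and NOLC1 fell from 2528 ± 18.9 to 1139 ± 44.5 CPM and from 630.2 ± 34.6 to 254.2 ± 19.1 CPM, and ODC1, the first enzyme of polyamine synthesis, from 491.4 ± 25.9 to 240.2 ± 2.71 CPM. Of 39 tested genes of G1/S and DNA replication, 26 fell and 2 rose (camera adjusted p = 2.97e-05, and adjusted p = 0.0622 with an estimated correlation). RRM2, a ribonucleotide reductase subunit, fell by 0.91, the helicase subunit MCM4 by 0.70 and the polymerase subunit POLD3 by 0.71 on the log2 scale, while RPA2 (0.37) and TK1 (0.38), named after their values were seen, rose. Of 35 genes of G2/M and mitosis, 16 fell and 4 rose (camera adjusted p = 0.00278, and adjusted p = 0.305 with an estimated correlation). The mitotic kinase PLK1 went from 287.7 ± 20.7 to 121.0 ± 7.36 CPM, with BUB1B of the spindle checkpoint at -1.25 and the condensin subunit NCAPH at -0.71. The 4 that rose, named after their values were seen, were CDC25C (0.55), BIRC5 (0.53), CCNB2 (0.27) and UBE2C (0.33).

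Stress response lists passed in the upward direction with the preset correlation, and none did with an estimated one. In the list of amino acid starvation and the unfolded protein response, 17 of 28 rose and 2 fell (camera adjusted p = 2.40e-12, and adjusted p = 0.0927 with an estimated correlation). ASNS, the asparagine synthetase, rose from 91.3 ± 8.36 to 388.4 ± 11.9 CPM, DDIT4 from 35.04 ± 1.40 to 141.2 ± 9.63 CPM and SESN2, a leucine sensor that inhibits mTORC1, from 9.97 ± 1.26 to 63.2 ± 4.56 CPM. Among genes named after their values were seen, the transcription factors ATF4 (0.85) and DDIT3 (1.64) and the serine synthesis genes PHGDH (1.17) and PSAT1 (1.11) rose, the endoplasmic reticulum chaperones HSPA5 (-0.11), HSP90B1 (-0.13) and CALR (-0.18) did not pass, and PDIA4 (-0.46) and the amino acid transporter SLC7A5 (-0.59) fell.

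Of 28 tested targets of the antioxidant regulator NRF2, 17 rose and 5 fell (camera adjusted p = 1.66e-08, and adjusted p = 0.0622 with an estimated correlation). The aldo-keto reductases AKR1C1, AKR1C2 and AKR1C3 rose by log2 fold changes of 3.52, 2.81 and 2.42; they are close paralogs whose reads may have been divided uncertainly. The 5 that fell, named after their values were seen, were GSR (-1.09), GCLM (-1.07), TXNRD1 (-1.10), UGDH (-0.43) and ALDH3A1 (-0.42). Of 22 hypoxia response genes, 11 rose and 2, P4HA1 (-0.46) and SLC2A1 (-0.38), named after their values were seen, fell (camera adjusted p = 0.00154, and adjusted p = 0.128 with an estimated correlation). CA9, a carbonic anhydrase, rose from 3.93 ± 1.19 to 19.5 ± 3.35 CPM, with ANGPTL4 at 2.13 and NDRG1 at 0.96. Of 24 p53 targets, 7 rose and 8 fell with the main scaling (9 and 4 with upper-quartile scaling, median 0.12), where the passing test (camera adjusted p = 0.0446, and adjusted p = 0.182 with an estimated correlation) came with a mean of 0.51 and a median of -0.04 log2 fold change. GDF15, at 7.01 the largest rise among the named genes, and BBC3 (3.14), an apoptosis promoter, belong to it, as does SESN2. CDKN1A, named after its values were seen, did not pass (-0.08). The call of this list ended without either shVec replicate 1 (0.0559) or shVec replicate 3 (0.0615), without replicate 3 of both groups (0.0508), with limma-voom (0.764), with the replicate number as a block (0.0522) and with the length offset (0.0642).

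Signalling lists were mixed. Of 21 targets of the transcriptional coactivator YAP, 10 rose and 6 fell (camera adjusted p = 0.00563, and adjusted p = 0.394 with an estimated correlation; 0.0687 with limma-voom). The matricellular protein CCN2 rose from 16.1 ± 0.58 to 57.5 ± 3.03 CPM and AXL also belongs here, while tissue factor, F3, fell from 36.9 ± 1.18 to 8.31 ± 0.81 CPM. Growth factor and immediate early genes had 16 higher and 10 lower of 32 (camera adjusted p = 0.667), the sign of the list turning with the length and GC offsets, and included falls of CCND1, cyclin D1 (192.1 ± 14.3 to 65.3 ± 1.17 CPM), and of the EGFR ligand EREG (103.4 ± 14.1 to 20.9 ± 1.64 CPM). Of 23 NF-kB and inflammatory genes, 8 rose and 7 fell (camera adjusted p = 0.636, direction down, median -0.04 and mean 0.37). The chemokines CXCL8 and CXCL1 fell by 2.52 and 2.27 on the log2 scale. Of 27 interferon response genes, 7 fell, with IFI6 at -1.65 and SAMD9 at -1.66, and 1 rose, IFIT2 (1.01, named after its values were seen), without the list passing (camera adjusted p = 0.102).

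Neither list of energy metabolism passed. Glycolysis genes had 7 higher and 11 lower of 24 (camera adjusted p = 0.308, direction down, median -0.11 and mean 0.03), with hexokinase HK2 at -1.40 and lactate dehydrogenase LDHB at -0.86. In oxidative phosphorylation 26 of 33 genes did not pass, 4 rose and 3 fell (camera adjusted p = 0.989), and the list's sign changed with the setting. With upper-quartile scaling 11 were higher and 2 lower, and with offsets for length and GC 3 were higher and 12 lower. With the main scaling, the 3 that fell were CYCS (-0.49), NDUFS1 (-0.55, and -0.30 with offsets for length and GC) and, named after its values were seen, SDHA (-0.27). The 4 that rose, named after their values were seen, were NDUFA1 (0.53), NDUFB3 (0.48), ATP5PO (0.38) and COX5A (0.32).

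Markers of cells other than epithelium were sparse. Only 7 of 22 leukocyte markers could be tested, of which CD8A (2.501 ± 0.27 to 4.76 ± 0.60 CPM) and CD4 rose (camera adjusted p = 0.791, median -0.07 and mean 0.33). CD4 had 9 counts over the shVec libraries and 54 over the shSOX2 libraries, a ratio of 5.50 with a 95% counting interval of 2.69 to 12.7. Its call was lost when any library other than shVec replicate 1 was left out, with edgeR adjusted p from 0.0624 to 0.140, and its log2 fold change of 2.39 was 3.93 without shVec replicate 1. Of 6 tested fibroblast and endothelial markers, COL1A1 (6.18 ± 0.74 to 15.4 ± 0.87 CPM), THY1 (2.65 ± 0.77 to 9.71 ± 1.01 CPM) and ACTA2 (0.79) rose and LUM (-3.53) fell, the last pair named after their values were seen (camera adjusted p = 0.131). COL1A1 stood at 0.86 with the GC offset. COL1A1, THY1 and ACTA2 are also members of the mesenchymal list.

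The largest changes included genes outside these lists, which were not tested as a group. Among the 10 largest rises were EEF1A2, a translation elongation factor otherwise typical of neurons and muscle (2.96 ± 0.47 to 118.6 ± 11.4 CPM), the stress-induced regulator NUPR1 (1.91 ± 0.20 to 75.8 ± 14.9 CPM), the activin subunit INHBE (4.18), the keratin KRT80 (3.73), the vesicle GTPase RAB3B (3.60), the AP-1 family repressor JDP2 (3.55) and the lipid-sensing nuclear receptor PPARG (1.01 ± 0.03 to 10.8 ± 0.95 CPM). GDF15 itself went from 0.64 ± 0.12 to 81.8 ± 9.75 CPM (log2 fold change 7.01 ± 0.17, edgeR adjusted p = 6.11e-09). Among the 10 largest falls were the collagenase MMP13 (215.0 ± 16.3 to 9.38 ± 1.09 CPM), PRODH, the proline dehydrogenase (18.3 ± 1.68 to 1.08 ± 0.33 CPM), and the chloride channel ANO1 (34.1 ± 3.12 to 3.92 ± 0.70 CPM).

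Libraries also differed in how counts varied with gene length. Across 9599 genes, which are not independent replicates, the deviation of a library from its own group's mean correlated with length at Spearman's rho of -0.60, 0.14 and 0.60 in shVec replicates 1, 2 and 3 and of 0.43, 0.35 and -0.51 in the shSOX2 replicates. The slope per doubling of length was 0.08 ± 0.12 (SD) in shVec and -0.08 ± 0.07 in shSOX2 on the log2 scale (two-sided exact permutation test, p = 0.2). Fold changes correlated with length at rho = -0.29 and with GC content at rho = 0.37 over the same genes.

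**Figure D3:**
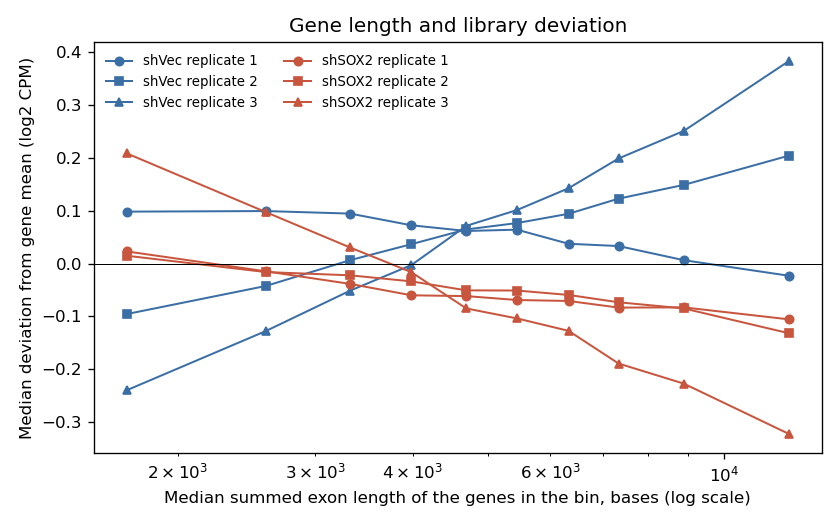
Median deviation of each library from the gene mean (log2 CPM, vertical axis) in 10 bins of genes ordered by summed exon length (bases, log axis). The line of shVec replicate 3 goes from -0.24 in the shortest bin to 0.38 in the longest and that of shSOX2 replicate 3 from 0.21 to -0.32, with the other 4 libraries between them in both bins.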

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

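The total-count scaling, the length and GC offsets and the removal of replicate 3 from both groups were chosen after the results were seen; the other alternatives were planned. In the simulations, with 200 changed genes per draw, a log2 change near 0.4 or -0.5 was called in a minority of genes. Far more genes were called in the real comparison, which makes its adjusted threshold less strict, so these shares do not carry over to it. Genes such as ACSL5 and CD4 rest on few counts. The number of called genes (7974) ranged from 6251 to 8844 over libraries left out, and was 7975 with DESeq2, 8018 with limma-voom and 7055 without replicate 3 of both groups. Genes at least 2-fold lower numbered 488 with upper-quartile factors against 738, and 554 to 1008 with a library left out; the cause was not tested. SOX2 stayed lower in all 18 alternatives, from -0.68 with the length offset to -0.25 with upper-quartile factors. Of 1924 values of the 107 named genes, 1907 kept their direction and their side of the threshold, 11 lost the call, 4 gained it and 2 changed sign. The 2 sign changes were KAT2A, at 0.0436 with upper-quartile factors and 0.0125 with total counts. No call shared with the main analysis had the opposite sign, except 47 genes with the GC offset and 66 with both offsets.

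Of the 32 lists, 15 passed, 3 with an estimated correlation and 26 with fry, which does not compare a list with other genes; over libraries left out, 12 to 16 passed. Oxidative phosphorylation had a median near 0 (camera adjusted p = 0.989) and changed sign with DESeq2 size factors (0.987), DESeq2 (0.944), no filter (0.949), the length offset (0.421), both offsets (0.732) and without replicate 3 of both groups (0.236); with a library left out it ranged from 0.454 to 0.942. The growth factor list changed sign with the length offset (0.824), the GC offset (0.407) and both (0.278), the triglyceride list with the GC offset (0.801) and both (0.870), and the deacetylase list with the GC offset (0.964). None of these passed, and the cause was not tested.

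The deviations gave no sign that replicate numbers pair the libraries: same-numbered ones correlated at -0.595, 0.157 and -0.750. No shSOX2 replicate correlated best with its own number. Replicates 1 and 2 did so with shVec replicate 3 (0.597 and 0.548), and replicate 3 with shVec replicate 1 (0.752). These deviations also followed gene length, so a pairing hidden by that trend cannot be excluded. A replicate block called 5982 genes, of which 5976 were called without it. EP300 (edgeR adjusted p = 0.0507), CD4 (0.0826) and the p53 list (camera adjusted p = 0.0522) no longer passed, and the oxidative phosphorylation list changed sign (0.989). The block changed no other call among the named genes and lists. Over alternatives the adjusted p of the p53 list ranged from 0.000286 with fry to 0.764 with camera after limma-voom. Scaling and shares of yeast reads were not run.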

Other observations

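The gene families, gene types and trend offsets below, and the tests of SOX2-OT reads, of mixed cells and of the size of the length trend, were chosen after results were seen; the splits, the tests without 1 library and the tests on random lists were written down before their values. Families were formed from gene symbols with at least 10 tested members, and 13 of 140 passed camera with the preset correlation, while none did with an estimated correlation (lowest adjusted p = 0.471). Core and linker histone genes rose in 17 of 23 tested cases and fell in 0, with a median log2 fold change of 1.13 (camera adjusted p = 4.11e-06). H2BC21 went from 3.09 ± 0.51 to 17.01 ± 1.29 CPM (SD, n = 3). Many histone genes are near-identical copies and make transcripts without a poly(A) tail, so their counts are uncertain. HOX genes, the positional regulators of the body axis, rose in 20 of 29 cases and fell in 0 (camera adjusted p = 0.000292), and HOXB9 went from 4.51 ± 0.94 to 29.1 ± 1.66 CPM. Genes of nuclear pores (NUP) fell in 18 of 21 cases, ribosomal RNA processing factors (UTP) in 10 of 11, and RNA helicases in 21 of 33 (DDX) and 11 of 16 (DHX), with UTP20 going from 128.0 ± 17.8 to 41.1 ± 5.05 CPM.

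Noncoding genes that were called were more often higher, with the main scaling; this was not tested against coding genes of like abundance. Of 732 tested lincRNA genes, 229 rose and 32 fell with a median log2 fold change of 0.53, and of 993 antisense genes 219 rose and 46 fell (median 0.35), and of 643 processed pseudogenes 84 rose and 39 fell (median 0.23), against 3172 higher and 3747 lower of 13284 protein-coding genes (median -0.03). Other families that passed were keratins (7 higher and 12 lower of 23), WDR (5 and 27 of 51), TAF (1 and 13 of 20), PRPF (1 and 8 of 13), semaphorins (8 and 1 of 16), claudins (5 and 1 of 11) and tetraspanins (9 and 1 of 16).

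The 10 possible splits of 6 libraries into 3 and 3 are too few for a share under 0.05. The real split called 7974 genes, 1 of 10 splits gave as many, and the highest of the other 9 called 0 with edgeR, 0 with limma-voom and 1 with DESeq2, with up to 547 genes at an unadjusted p under 0.05. Each of those 9 puts shVec and shSOX2 libraries in the same group, so a difference between them enters the spread. Their low counts therefore do not measure false calls.

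SOX2 transcript fell little beside many other genes. The tables argue against reads of the overlapping gene SOX2-OT counted as SOX2, since SOX2-OT reached at most 0.688% of the SOX2 reads per kilobase in any library. They argue against control-like cells mixed with cells of full SOX2 loss in the shSOX2 libraries, since no gene could then fall by more than SOX2 and 738 genes were called at least 2-fold lower. A mixture with partial loss in the other cells stays open. They argue against a single library, since the lowest log2 change without 1 library was -0.46. A loss larger in SOX2 protein than in its transcript, or an effect of the hairpin on other genes, may account for it; neither was tested, and no second hairpin was analysed here.

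Lists were lower while a trend with gene length differed between libraries. With offsets for length and GC the basal squamous list still passed (camera adjusted p = 3.05e-62), and the length trend gave its genes a median log2 change of -0.04, relative to the median gene, where -1.14 was measured, which argues against the trend as the whole cause. The G2/M list also passed with those offsets (0.00121), but with a median of 3932 exonic bases it is not one that the trend would lower, so that pass decides nothing. The trend gave its genes 0.02 by the same measure, above the list's measured median of -0.25 and both of its quartiles (-0.63 and -0.01). That value argues against the length trend as the cause of this list's fall. The acetyltransferase list had a median log2 change of -0.44 (interquartile range 0.62) before and -0.40 (0.47) after those offsets, where its adjusted p was 0.0411. With the length offset alone the median was -0.38 (0.46) and the call ended (0.0627). The median of all genes went from 0.03 to -0.10 with that offset and to -0.09 with both. The list thus stood less far below it in either case. The offset and the form of the set test changed together, so what ended the call was not tested. The written bound was a pass after the correction, but it was met narrowly, and the trend of -0.17 by the same measure lies between the quartiles of the list (-0.75 and -0.13), so the trend as whole cause and a lower level of these genes cannot be told apart. Part of the trend lies between the groups, and the offsets would remove a true change that follows length.

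HOX genes were higher in shSOX2. With offsets for length and GC the family still passed, with an unadjusted camera p of 0.000234 and 15 of 29 genes higher, which argues against the trend as the whole cause. Their median log2 change of 0.99 lay at percentile 100 of 10000 random lists matched on abundance, whose median was 0.22 with 0.57 as the upper end of their central 95%, which argues against a rise shared by all genes of low abundance. In the 18 alternatives, 14 to 20 HOX genes were called higher and 0 lower. What raised them was not tested. The family did not pass camera with an estimated correlation (adjusted p = 0.471), which leaves its call open. That loss need not come from correlation between the genes. Squamous terminal differentiation, with an estimated correlation of 0.0102 against the preset 0.01, also lost its pass (camera adjusted p = 0.0622).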
